A study of Mus musculus with 6 samples.

How the data were processed

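The series compared 2 groups of mouse leukaemias, 3 Cdh1-intact and 3 Cdh1-deficient, on 6 one-colour Affymetrix expression arrays. Per the labels, donors carried a conditional gene-trap allele of Cdh1, an activator of the anaphase-promoting complex (APC/C), with or without an inducible Cre recombinase, and came from shared litters. Marrow cells received a retroviral vector with N-myc and green fluorescent protein (GFP), and the GFP-positive marrow mononuclear cells of each moribund mouse were sorted for RNA. Each array was therefore taken as 1 mouse. Groups and replicate numbers were taken from the sample labels.

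The deposited table holds 1 log2 value per probe set and array for 45101 probe sets. The authors made these log2 values with RMA, per the submitters' processing notes, which give no version. RMA corrects background, quantile-normalizes probes between arrays and summarizes the probes of a set on the log2 scale. It makes array distributions alike, so a change of the total RNA per cell cannot be seen in these values. Array medians lay between 5.07 and 5.13 and lower quartiles between 3.75 and 3.83. No detection call was used here, and levels near 3 to 4 were taken as close to the floor. The number of arrays limits the precision.

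Probe sets were named from the platform annotation of 2016. It listed 35890 of the probe sets. The other 9211 are unnamed here, and 64 control probe sets were left out. Of the listed sets 932 carried several gene symbols and were not used, and 34945 carried 1 symbol, of which 34741 matched a gene identifier in a RefSeq gene table of assembly GRCm38.p6 and 0 needed a newer symbol. That table was used for names, gene order and chromosomes only, and the genome build behind the arrays is not given in the sources used here. Each gene was represented by the probe set with the highest mean over the 6 arrays, which gave 18193 genes, 9183 of them with a single probe set. There was no filter on level. Trp53, Ccnb1 and Ddx3y, which the naming rule asked for, were not analysed here.

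Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, two-sided). This is the tool the series description names. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Differences are Cdh1-deficient minus Cdh1-intact on the log2 scale, with the moderated standard error (SE). A permutation of 3 against 3 arrays has 10 splits and a smallest two-sided p of 0.1, so no permutation p was used for single genes.

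Before the data were examined, 30 gene lists were fixed from textbook knowledge of the cell cycle, B-cell development and the other cell types of marrow. They were tested with camera at the preset inter-gene correlation of 0.01, adjusted over the lists, with at least 5 measured members required. The list of replication-dependent histones fell short of this, and 29 were tested. Of 728 distinct list genes 660 were measured. An estimated correlation per list and fry were alternatives. fry asks whether the genes of a list move one way on balance and does not compare them with other genes.

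The genes named were also fixed by rule before the data were examined. They were a fixed set around Cdh1, N-myc and the G2/M checkpoint, and the 12 most changed genes in each direction. Where fewer passed the threshold, the 12 were filled with the genes of smallest unadjusted p in that direction, given as values that did not pass. Further named genes were up to 2 members per list by the same order, and the sex-linked transcripts Xist, Ddx3y, Eif2s3y, Kdm5d and Uty. Predicted genes without a proper symbol were passed over. Genes named outside the rule are said to be so.

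Alternatives fixed at the same time were quantile normalization, median centring, 2 filters on level, the mean of all probe sets of a gene, probe sets with shared-target suffixes left out, all probe sets tested, trend and robust estimation, array weights, other thresholds, the replicate number as a block, Xist as a covariate, sex-linked transcripts left out, and each array left out in turn. Leaving out chromosomes 3 and 5, and Cdh1-intact array 2 with trend and robust estimation, was added after seeing the data. The grouping by chromosome used the 9079 genes with a mean level at or above the median of all genes and was also chosen after seeing the data.

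The gene test was also tried on simulated data. Values for the 18193 genes were drawn independently around the real gene means with each gene's spread within groups, with 200 genes changed in each of 10 runs. With adjusted p under 0.05 it recovered 45.6% of genes changed by 1 on the log2 scale. For those changed by 2, 3 and 4 it recovered 78.6%, 92.0% and 95.2%, with 8.1 false calls per run. These rates hold for independent values with 200 changed genes, so they do not give the share of changes found in the real data. The list test found 50 of 50 lists shifted by 0.5 and called 3 of 150 that were not. Among 1000 random lists of 30 genes in the real data, 27 had an unadjusted p under 0.05. Genes of the simulated lists were independent, and those of the random lists were not chosen for a shared function. Neither check therefore measures false calls for lists of co-regulated genes. In the real lists the estimated correlation ran from −0.06 (adhesion and homing) to 0.79 (neutrophils and granulocyte precursors). Plots were made with matplotlib 3.10.9.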

Results

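Gene expression was measured in GFP-positive marrow cells of mice moribund with N-myc-induced B-cell acute lymphoblastic leukaemia. The cells were Cdh1-intact in 3 mice and Cdh1-deficient in 3, with 1 array per mouse and 18193 genes in the comparison. The Cdh1 of this study is the product of the mouse gene Fzr1, a coactivator that directs the APC/C ubiquitin ligase to mitotic cyclins and kinases late in mitosis and in G1. The mouse symbol Cdh1 belongs to E-cadherin, an epithelial adhesion protein, whose probe set lay near the floor at 3.14 ± 0.12 in Cdh1-intact and 3.03 ± 0.08 in Cdh1-deficient cells (log2, SD, n = 3 each). The comparison addressed how the expression signature of leukaemia cells differed without Cdh1.

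Fzr1, measured by a single probe set (chromosome 10), was read first because it bears on the group labels. Its log2 level was 8.92, 8.04 and 8.92 on the Cdh1-intact arrays 1, 2 and 3, and 8.10, 7.73 and 8.22 on the Cdh1-deficient arrays. The difference of −0.61 (SE 0.28) did not pass the limma test (adjusted p = 0.849), and the groups overlapped at Cdh1-intact array 2. Without that array the difference was −0.91 (SE 0.17, adjusted p = 0.801). The allele is a gene trap with a floxed cDNA, and where the probes lie relative to the trap is not given in the sources used here. A probe outside the disrupted part checks nothing, so these values neither settle the genotype of an array nor contradict its label. The chosen probe set of Mycn, the gene for N-myc, lay at 13.35 ± 0.20 in Cdh1-intact and 13.62 ± 0.12 in Cdh1-deficient cells (log2, SD, n = 3 each). Its other probe sets read 6.31 to 8.51 and 2.84 to 3.23 over the 6 arrays, so the level depended on the probe set.

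The arrays differed in cell lineage transcripts within the Cdh1-intact group. Cd79b, Ms4a1, Cd3g, Gzma and S100a8 were named here outside the rule, after their values were seen. On Cdh1-intact array 2 the B-cell receptor gene Cd79b lay at 4.35 against 11.60 to 12.47 on the other arrays, and the B-cell surface gene Ms4a1 at 3.97 against 8.68 to 10.87. On that array the T-cell receptor complex genes Cd3d and Cd3g lay at 12.55 and 12.48, and the cytotoxic granule gene Gzma at 12.39. Cdh1-intact array 3 was intermediate, with Cd3d at 8.69, Cd3g at 7.95 and Gzma at 8.33, beside B-cell transcripts at the level of the remaining arrays. S100a8, a calprotectin subunit of neutrophils, lay at 9.13 on Cdh1-intact array 2 and at 12.63 to 13.87 elsewhere. The first principal component carried 58.2% of the variance and set Cdh1-intact array 2 (96.2) apart from the other 5 arrays (−22.9 to −12.7). Across genes this array correlated at r = 0.933 to 0.945 with the others, which correlated at 0.979 to 0.993 among themselves. Genes are not independent replicates. Xist, which is expressed from the inactive X of females, lay at 6.75 on Cdh1-intact array 1 and at 12.58 to 13.17 on the others, and the Y-linked Eif2s3y at 9.60 on array 1 and 2.68 to 3.22 on the others. The chosen probe sets of Kdm5d and Uty, also Y-linked, lay between 3.13 and 4.27 on all arrays, while another Kdm5d probe set lay at 6.81 on Cdh1-intact array 1 and at 2.65 to 3.15 on the others.

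**Figure D1:**
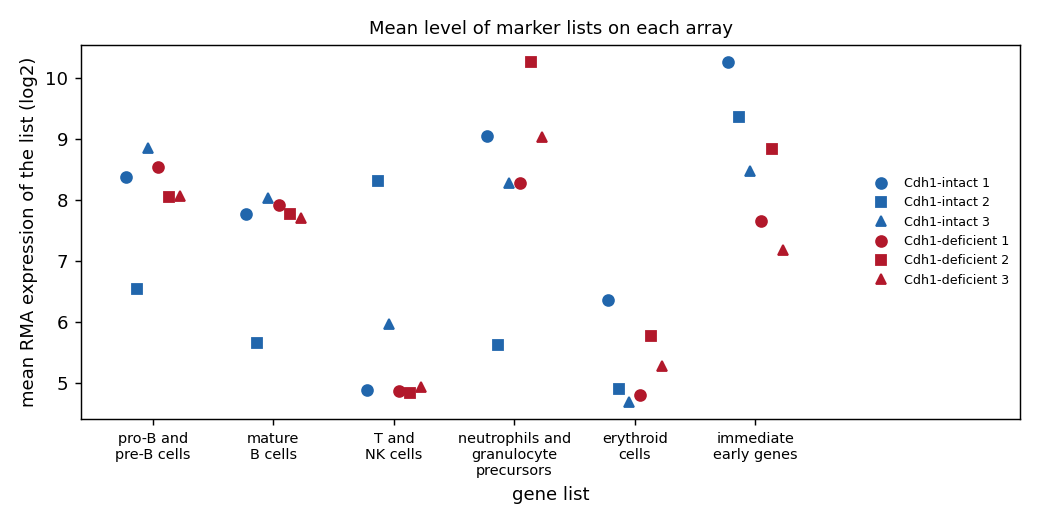
Mean log2 RMA level of 6 marker lists on each of the 6 arrays, with blue symbols for Cdh1-intact and red symbols for Cdh1-deficient arrays. Cdh1-intact array 2 (blue square) has a T and NK cell mean of 8.31 against 4.83 to 5.97 on the others. Its B-cell and neutrophil means are lower than those of the others. Cdh1-intact array 1 (blue circle) has the highest erythroid mean, 6.36 against 4.68 to 5.78.

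No single gene passed the threshold between Cdh1-deficient and Cdh1-intact cells. With limma 0 of 18193 genes had an adjusted p under 0.05 and the lowest adjusted p was 0.849. At an unadjusted p under 0.05 there were 1000 genes, 729 higher and 271 lower in Cdh1-deficient cells, which is 5.50% where chance alone gives 5%. The 3 arrays of one group all lay above those of the other for 2135 genes, 1209 higher and 926 lower, or 11.7% where chance gives 10%. The median difference over all genes was 0.0034, and the median within-group SD 0.197. The genes below are therefore values that did not pass.

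Among the 12 genes of smallest p in the upward direction, Camkk2, a calcium/calmodulin-dependent kinase kinase, had a log2 difference of 0.88 (SE 0.10), from 8.93 ± 0.06 to 9.81 ± 0.11 (SD, n = 3 each). The deubiquitinase Usp2 differed by 1.43 (SE 0.19) and the matrix glycoprotein Sparc by 2.29 (SE 0.38), from 5.32 ± 0.42 to 7.61 ± 0.65 (SD, n = 3 each). The others were Mtus1 (1.96), Rad9b (1.30), Ccnc, which encodes cyclin C (0.91), Fam185a (0.89), Gatc (0.87), Mrpl49 (0.76), Celsr2 (0.74), Gmeb1 (0.71) and Atxn2 (0.63). Camkk2, Fam185a, Gatc, Atxn2 and Rad9b lie on chromosome 5 and Celsr2 on chromosome 3. Several rested on the chosen probe set. With the mean of all probe sets of a gene the difference was 0.04 for Ccnc, 0.19 for Gmeb1, 0.36 for Atxn2, 0.45 for Celsr2, 0.66 for Rad9b and 1.42 for Sparc, and without the shared-target probe sets it was −0.02 for Atxn2 and 1.02 for Mtus1.

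In the downward direction the lymphocyte activation antigen Cd69 had the lowest p and the largest difference of the 12, −3.62 (SE 0.48). Its levels were 9.93, 10.24 and 8.46 on the Cdh1-intact arrays and 6.09, 6.08 and 5.61 on the Cdh1-deficient arrays. The immediate early transcription factor Fosb differed by −3.08 (SE 0.61) and the phosphatase gene Dusp2 by −1.42 (SE 0.31). The ceramide synthase gene Cers4 differed by −1.34 (SE 0.21). The others were Creg1 (−0.98), Brwd1 (−0.85), Zfp800 (−0.81), Trim2 (−0.77), Nenf (−0.70), Cndp2 (−0.51), Stx8 (−0.49) and Mdp1 (−0.42). With the mean of all probe sets Zfp800 was at −0.35, Brwd1 at −0.54, Trim2 at −0.43 and Mdp1 at −0.23.

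**Figure D2:**
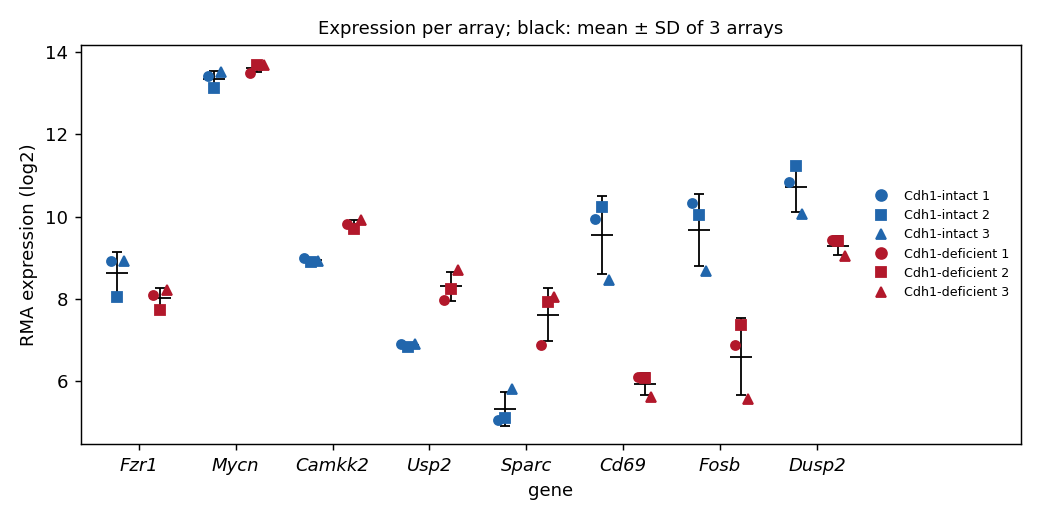
Log2 RMA level of 8 genes on each array (blue, Cdh1-intact; red, Cdh1-deficient), with the mean and SD of the 3 arrays of each group in black. Camkk2, Usp2 and Sparc lie higher and Cd69, Fosb and Dusp2 lower on every Cdh1-deficient array, and Fzr1 and Mycn overlap between the groups.

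Of the mitotic and checkpoint genes fixed for naming, none passed. The p53-inducible cell cycle inhibitor Cdkn1a differed by −0.55 (SE 0.23), with all 3 Cdh1-deficient arrays (6.43 to 6.88) below the Cdh1-intact arrays (6.89 to 7.64). The APC/C-Cdh1 substrates Plk1, Cdc20 and Aurka differed by 0.34 (SE 0.22), 0.19 (SE 0.21) and 0.08 (SE 0.11), and Aurka by −0.13 with the mean of its probe sets. The G2/M checkpoint kinases Chek1 and Wee1 differed by 0.29 (SE 0.39) and 0.22 (SE 0.35). Cdh1-intact array 1 carried the lowest values of both, 8.30 and 8.27, and the differences turned to −0.15 and −0.18 without it and to −0.07 and −0.11 with Xist as a covariate. Myc differed by −0.05 (SE 0.18) and turned to 0.13 without that array, 0.03 without Cdh1-deficient array 2 and 0.09 with Xist as a covariate. Xist was low on Cdh1-intact array 1 alone, so the covariate acts much like leaving that array out.

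Genes of mitosis were higher as a group in Cdh1-deficient cells, a call that rested on the preset correlation. Of 36 spindle and chromosome segregation genes 32 were higher, with a median log2 difference of 0.30 (camera adjusted p = 3.03e-05; adjusted p = 0.731 with an estimated correlation). Aspm, needed for spindle pole focusing, differed by 0.65 (SE 0.23) and the kinesin gene Kif2c by 0.60 (SE 0.24), or 0.22 with the mean of its probe sets. The APC/C-Cdh1 substrate transcripts rose by a median of 0.18, with 29 of 40 higher (camera adjusted p = 0.0102; adjusted p = 0.832 with an estimated correlation). Ect2, a gene of cytokinesis on chromosome 3, differed by 0.78 (SE 0.18), and the transcription factor gene Ets2 by −1.85 (SE 0.55), or −0.97 with the mean of its probe sets. DNA damage checkpoint and repair genes rose by a median of 0.12, with 28 of 33 higher (camera adjusted p = 0.0304; adjusted p = 0.832 with an estimated correlation), among them the checkpoint kinase gene Chek2 on chromosome 5 at 0.84 (SE 0.27) and Mdc1 at 0.60 (SE 0.21). MYC target and ribosome biogenesis genes rose by a median of 0.10, with 31 of 39 higher (camera adjusted p = 0.0102; adjusted p = 0.731 with an estimated correlation). Cad, a pyrimidine synthesis enzyme on chromosome 5, differed by 0.61 (SE 0.17) and the cap-binding factor Eif4e, on chromosome 3, by 0.26 (SE 0.09), which became 0.33 and 0.12 with the mean of all probe sets. With fry the adjusted p was 0.615 for the spindle and MYC lists, 0.835 for the substrates and 0.841 for the checkpoint list. No member of these 4 lists passed when adjusted over the list alone or over all genes. The mean levels of the lists overlapped between the groups except for the MYC list, which separated only narrowly. MYC list means were 11.21, 11.23 and 11.35 on the Cdh1-intact and 11.40, 11.36 and 11.43 on the Cdh1-deficient arrays. Substrate means were 9.53, 9.74 and 9.91 on the Cdh1-intact and 9.86, 9.77 and 9.86 on the Cdh1-deficient arrays, and spindle means 9.23, 9.31 and 9.59 against 9.56, 9.68 and 9.74.

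Several of these calls were lost with 1 array left out. Without Cdh1-intact array 1, the substrate list had a median of 0.09 (adjusted p = 0.369), the checkpoint list −0.02 (0.872) and the MYC list 0.12 (0.0614), which was no smaller than with all arrays. On that array the mean level of the checkpoint list was 8.50, the lowest of the 6, against 9.05 on Cdh1-intact array 2 and 9.03 to 9.05 on the Cdh1-deficient arrays. The checkpoint list also missed without Cdh1-deficient array 2 (median 0.16, adjusted p = 0.0548) or 3 (0.13, 0.0643), with no smaller a median, and the MYC list without Cdh1-intact array 2 (0.06, 0.0741). The spindle list passed in each of the 6 fits that left out 1 array, and all 4 lists passed with the genes of chromosomes 3 and 5 left out. In that last setting the MYC median fell to 0.06 (camera adjusted p = 0.0372). With genes below the median probe set level left out, the substrate (adjusted p = 0.158), checkpoint (0.214) and MYC (0.158) calls were lost at unchanged medians, the checkpoint call also with quantile normalization (0.155) or with the lowest quartile of levels left out (0.0567), and the MYC call without shared-target probe sets (0.0516). Of 18 alternatives the spindle list passed in 16, the substrates in 14, the MYC list in 12 and the checkpoint list in 10.

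Immediate early genes, which respond within minutes to growth factors, receptor signals or stress, fell in Cdh1-deficient cells. All 21 measured members were lower, with a median of −1.42 (camera adjusted p = 3.25e-10; adjusted p = 0.731 with an estimated correlation). Of the 21, 9 had an unadjusted p under 0.05, 2 passed when adjusted over the list alone (Fosb and Dusp2) and 0 passed over all genes. The list also held Fos, which went from 12.76 ± 0.38 to 10.32 ± 1.83, and Klf6, from 9.26 ± 0.96 to 7.44 ± 0.42 (SD, n = 3 each, both chosen after their values were seen). List means were 10.28, 9.36 and 8.48 on the Cdh1-intact arrays and 7.66, 8.85 and 7.18 on the Cdh1-deficient arrays, so the groups overlapped. The call held in each of the 6 fits that left out 1 array, and the median without Cdh1-intact array 2 was −1.39. With fry the adjusted p was 0.615, so this call too rested on the preset correlation.

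Heat shock and unfolded protein response genes fell by a median of 0.20 on the log2 scale, with 15 of 21 lower (camera adjusted p = 0.0469; adjusted p = 0.832 with an estimated correlation). Atf4, a transcription factor of the integrated stress response, differed by −0.58 (SE 0.20), or −0.30 with the mean of its probe sets, and the co-chaperone gene Dnajb1 by −0.51 (SE 0.18). Interferon response genes fell by a median of 0.10, with 19 of 29 lower (camera adjusted p = 0.0430; adjusted p = 0.731 with an estimated correlation), including Irf7 at −0.59 (SE 0.16) and Rtp4 at −0.56 (SE 0.22). The heat shock call was lost without Cdh1-intact array 1 (median −0.22, adjusted p = 0.157), Cdh1-intact array 2 (−0.06, 0.149) or Cdh1-deficient array 3 (−0.13, 0.333). The interferon call was lost without Cdh1-intact array 1 (−0.06, 0.0561) or 3 (−0.04, 0.302) and without Cdh1-deficient array 1 (−0.11, 0.156) or 3 (−0.02, 0.191). Without chromosomes 3 and 5 both calls were lost (adjusted p = 0.108 and 0.0637), though the medians of −0.19 and −0.13 were about as large as or larger than before. The interferon call was also lost on ranks (0.0586), with the mean of all probe sets (0.0999) and without shared-target probe sets (0.0505), and the heat shock call on ranks (0.0586) and without shared-target probe sets (0.0568), so that they passed in 7 and 10 of 18 alternatives. Adhesion and homing genes missed the threshold with a median of −0.35 and 12 of 17 lower (camera adjusted p = 0.0512; adjusted p = 0.731 with an estimated correlation), and passed with fry (adjusted p = 0.00701). The list passed downward in 11 of 18 alternatives, among them without Cdh1-intact array 2 (0.0122), without Cdh1-deficient array 3 (0.0482) and without chromosomes 3 and 5 (0.0154). Without Cdh1-intact array 2 its median shrank to −0.22. Adgre5, an adhesion receptor of leukocytes, differed by −0.86 (SE 0.21) and the endothelial and leukocyte adhesion gene Pecam1 by −1.17 (SE 0.40).

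Transcripts of other blood cell types differed between the groups, and Cdh1-intact array 2 carried much of these differences. T and NK cell genes fell in Cdh1-deficient cells by a median of 1.13, with 19 of 21 lower (camera adjusted p = 3.03e-05; adjusted p = 0.731 with an estimated correlation). Cd3d differed by −3.83 (SE 1.54) and Cd2 by −1.02 (SE 0.28). Without Cdh1-intact array 2 the median was −0.36 (adjusted p = 0.000192), but of the remaining Cdh1-intact list means only that of array 3 (5.97) lay above the Cdh1-deficient arrays (4.83 to 4.93), and that of array 1 (4.89) lay among them. Neutrophil and granulocyte precursor genes rose by a median of 1.81, with 16 of 18 higher (camera adjusted p = 0.000528; adjusted p = 0.832 with an estimated correlation). The collagenase gene Mmp8 differed by 2.79 (SE 1.43) and Mmp9 by 1.84 (SE 0.94). Without Cdh1-intact array 2 that median was 0.36 (adjusted p = 0.118), and without Cdh1-deficient array 2, which had the highest list mean (10.27), the median was 1.38 (adjusted p = 0.234).

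The B-lineage lists did not pass. Pro-B and pre-B cell genes had a median of −0.01 and a mean of 0.29, with camera pointing downward (adjusted p = 0.755), and without Cdh1-intact array 2 they fell by a median of 0.33 (adjusted p = 0.000287). Mature B-cell genes had a median of 0.48 (adjusted p = 0.362), which turned to −0.17 (0.0671) without Cdh1-intact array 2 and passed at 1.02 (0.0305) without Cdh1-intact array 3, with the class II transactivator Ciita at 1.11 (SE 0.56) and Fcmr at 0.97 (SE 0.50). Receptor signalling genes had a median of 0.19 (adjusted p = 0.561), or −0.01 without Cdh1-intact array 2 and 0.35 without Cdh1-intact array 1, with Dapp1 at 0.65 (SE 0.29) and Nfkbia at −0.35 (SE 0.17). Plasma cell genes had a median of 0.13 (adjusted p = 0.622), or 0.01 without Cdh1-intact array 2, with Slamf7 at 1.49 (SE 1.05) and Jchain at 1.30 (SE 0.93). Single arrays weighed on both: Slamf7 lay at 4.37 on Cdh1-intact array 2 and at 7.31 to 8.67 elsewhere. Jchain lay at 8.59 on Cdh1-deficient array 2 and at 4.69 to 6.52 elsewhere. Of the mature B-cell genes, Ciita lay at 3.99 on Cdh1-intact array 2 and at 4.64 to 6.26 elsewhere, and Fcmr at 4.25 against 5.61 to 6.72. The recombinase gene Rag1 was at −0.80 (SE 0.56) and the transcription factor gene Ikzf3 at −0.59 (SE 0.25). Rag1 lay at 5.36 on Cdh1-intact array 3 and near the floor, at 3.01 to 3.61, on the others.

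DNA replication genes did not pass (median 0.07, adjusted p = 0.302), although the polymerase gene Pole and the clamp loader gene Rfc2, both on chromosome 5, were at 0.61 (SE 0.17) and 0.34 (SE 0.12). Without Cdh1-intact array 1 the replication list turned to a median of −0.16 and passed downward (adjusted p = 0.00622), whereas it passed upward without Cdh1-intact array 2 (0.19, adjusted p = 0.00859) or 3 (0.21, adjusted p = 0.0157). APC/C subunits and regulators had a median of 0.11 (adjusted p = 0.302), which passed at 0.24 (0.0164) without Cdh1-intact array 3 and was 0.05 without Cdh1-intact array 2, with Anapc7 at 0.52 (SE 0.20) and Anapc4 at 0.39 (SE 0.17), both on chromosome 5. The G1/S regulators had a median of 0.11 (adjusted p = 0.424), with E2f5 at 0.95 (SE 0.35) and E2f8 at 0.66 (SE 0.27). E2f5 lay at 7.12 on Cdh1-intact array 2 and at 7.96 to 9.04 on the others. The p53 targets had a median of −0.11 (adjusted p = 0.182). They passed downward without Cdh1-intact array 3 (0.0276), without Cdh1-deficient array 2 (0.0234) and with genes below the median probe set level left out (0.0492), and their median was 0.02 without Cdh1-intact array 2. Named members were Dcxr at −0.56 (SE 0.18) and Btg2, which is also an immediate early gene, at −1.02 (SE 0.39). The BCL2 family and caspases (median 0.03, adjusted p = 0.576) held Birc2 at 0.42 (SE 0.17) and Diablo at 0.48 (SE 0.25). The MYC family network (median 0.08, adjusted p = 0.298) held Mxi1 at 0.84 (SE 0.32) and Mlxip at 0.83 (SE 0.33). Mxi1 lay at 8.92 on Cdh1-intact array 2 and at 9.49 to 10.60 on the others, and Mlxip at 8.00 against 8.89 to 9.76.

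Metabolic and ribosomal lists also did not pass. Glycolysis genes had a median of −0.08 (adjusted p = 0.576), oxidative phosphorylation genes −0.0017 (adjusted p = 0.424) and cytosolic ribosomal proteins −0.0014 (adjusted p = 0.673). Pdk1, a kinase that inhibits pyruvate dehydrogenase, was at 0.42 (SE 0.14) and the hexokinase gene Hk2 at 0.97 (SE 0.46). Hk2 lay at 7.46 on Cdh1-intact array 2 and at 8.88 to 9.62 on the others. Ndufa8 and Sdha were at −0.17 (SE 0.09) and −0.28 (SE 0.19), and Rpl14 and Rps6 at −0.39 (SE 0.19) and −0.24 (SE 0.16). Of the remaining cell type lists, stem and progenitor genes had a median of 0.05 (adjusted p = 0.870), with the cytokine receptor gene Flt3 on chromosome 5 at 1.86 (SE 0.67) and Cd34 at −0.21 (SE 0.13). Monocyte and macrophage genes had a median of −0.06 and a mean of 0.15, with camera pointing downward (adjusted p = 0.857), Lyz2 at 1.35 (SE 0.93) and Clec7a at 0.43 (SE 0.22). Lyz2 lay at 6.11 on Cdh1-intact array 2 and at 8.55 to 10.51 on the others. Erythroid genes had a median of −0.03 (adjusted p = 0.527), with Hba-a1, near the floor on all arrays, at −0.14 (SE 0.10) and Rhd at 0.39 (SE 0.32). Without Cdh1-intact array 1 the monocyte and erythroid medians turned to 0.36 and 0.38 and passed upward (adjusted p = 0.00622 and 0.0253), whereas the monocyte list passed downward without Cdh1-intact array 2 (−0.19, adjusted p = 0.0150). Platelet genes had a median of −0.05 (adjusted p = 0.367), with Clec1b at −0.52 (SE 0.39) and Gp1bb at −0.14 (SE 0.11), and mast cell, basophil and eosinophil genes 0.11 (adjusted p = 0.424), with Prg2 at 1.27 (SE 0.61) and Cpa3 at 0.41 (SE 0.35). Stroma and endothelium genes had a median of 0.01 with camera pointing downward (adjusted p = 0.576), and Sparc was the 1 member that passed when adjusted over the list alone.

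**Figure D3:**
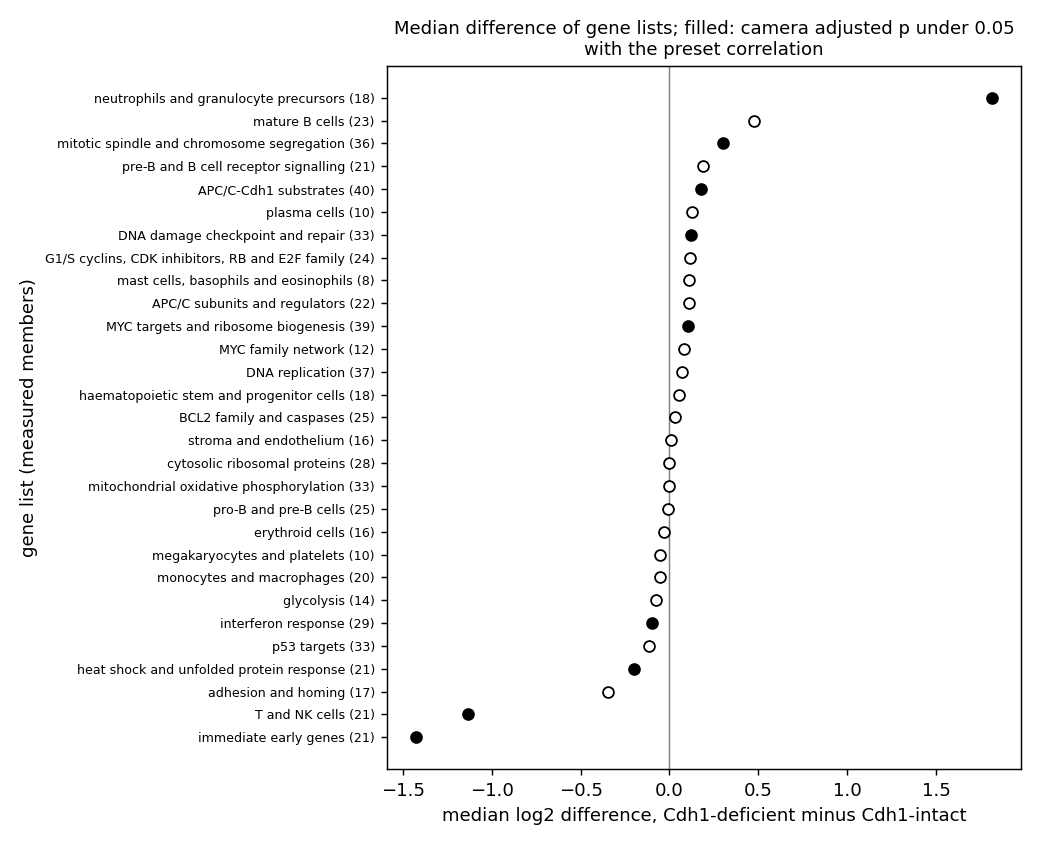
Median log2 difference (Cdh1-deficient minus Cdh1-intact) of the 29 gene lists, with the number of measured members in brackets and filled points for the 9 lists with a camera adjusted p under 0.05 at the preset correlation. Immediate early genes lie at −1.42 and neutrophil genes at 1.81. With an estimated correlation 0 of the lists passed.

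Genes on chromosomes 5 and 3 were higher together in Cdh1-deficient cells, in a grouping chosen after the values were seen. Among genes with a mean level at or above the median, 87.0% of 608 genes on chromosome 5 and 85.9% of 446 on chromosome 3 were higher, with median log2 differences of 0.36 and 0.31. The other 18 chromosomes had medians between −0.03 and 0.20, and between 44.9% and 75.9% of their genes were higher. The median over all 9079 genes of this set was 0.087. Of the 729 genes higher at an unadjusted p under 0.05, 43.6% lay on chromosomes 3 and 5, which held 11.2% of the genes tested. camera gave adjusted p = 7.05e-19 for chromosome 5 and 8.02e-11 for chromosome 3 (adjusted p = 0.329 and 0.344 with an estimated correlation), and fry 0.0557 and 0.0595. Chromosome 4, at 0.20, also passed upward with camera, and chromosomes 13 and 15, at −0.03 and 0.01, passed as lower than the rest (adjusted p = 0.738 for each of these 3 with an estimated correlation). After centring each array, the median of chromosome 5 was −0.12, −0.15 and −0.10 on the Cdh1-intact arrays and 0.13, 0.09 and 0.16 on the Cdh1-deficient arrays. For chromosome 3 it was −0.04, −0.15 and −0.12 against 0.01, 0.21 and 0.14. Single arrays stood apart elsewhere, such as Cdh1-intact array 3 on chromosome 19 (−0.46) and Cdh1-deficient array 2 on chromosome 13 (−0.27).

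**Figure D4:**
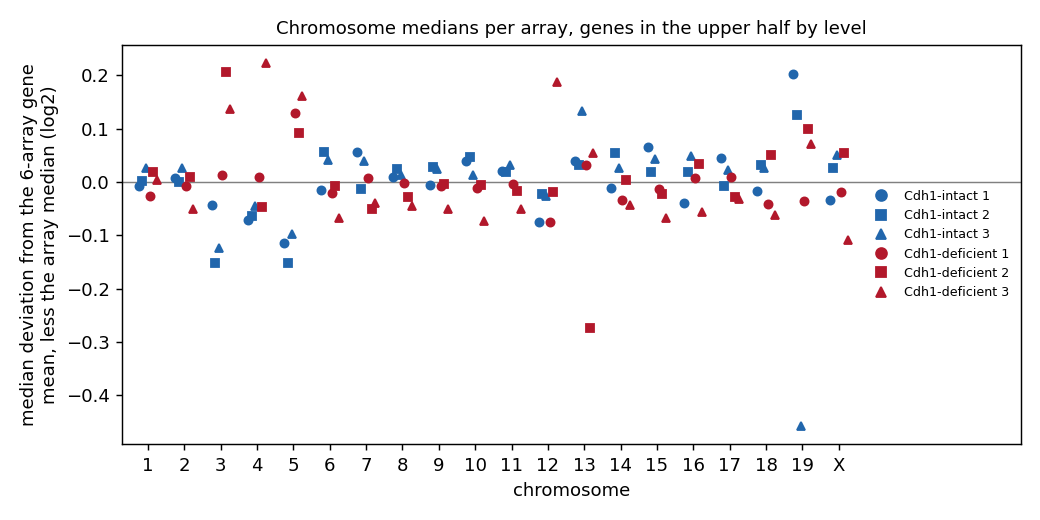
Median log2 deviation of the genes of each chromosome from their 6-array means, less the array's own median, for genes with a mean level at or above the median (blue, Cdh1-intact; red, Cdh1-deficient). On chromosomes 3 and 5 all 3 Cdh1-deficient arrays lie above all 3 Cdh1-intact arrays.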

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

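Of these alternatives, leaving out chromosomes 3 and 5 and the combined fit without Cdh1-intact array 2 were chosen after the result was seen. With limma, 0 genes passed in the main comparison and in 21 of 22 alternatives, and 1 passed with Xist as a covariate. That gene was Cym (−4.10, adjusted p = 0.0271), and the lowest adjusted p ranged from 0.0271 to 0.999 over the alternatives. Genes at an unadjusted p under 0.05 numbered 442 to 1751 over the 6 fits that left out 1 array, against 1000 with all arrays. Fzr1 stayed lower in Cdh1-deficient cells in all alternatives, at −0.91 to −0.46. The number of gene lists past the threshold was 9 with camera, 0 with an estimated correlation and 1 with fry. The list that passed with fry, adhesion and homing, was not among the 9. The number was 7 to 12 over the fits that left out 1 array and 6 to 10 in the other alternatives. The causes were not tested.

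Some lists reversed without Cdh1-intact array 1. Over the 6 fits that left out 1 array, the median ranged from −0.0188 to 0.24 for DNA damage checkpoint and repair, from −0.16 to 0.21 for DNA replication, from −0.19 to 0.36 for monocytes and macrophages and from −0.16 to 0.38 for erythroid cells. The cause was not tested. Cdh1-intact array 1 had the highest monocyte and macrophage list mean, 6.86 against 4.80 to 6.31 on the others. Its erythroid mean was also the highest (6.36 against 4.68 to 5.78) and its DNA replication mean the lowest (9.85 against 10.22 to 10.46). It alone had Xist low and Eif2s3y high, so a difference of sex cannot be told apart from these and its other traits. Among single named genes 23 of 1683 values under an alternative moved by more than the spread between replicates, 21 of them with the mean of all probe sets. Many of the 1683 could not move. The replicate block, filters on level and trend estimation leave the difference of a gene unchanged. With the mean of all probe sets, 21 of 91 genes moved.

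The deviations of same-numbered arrays from their group means correlated at −0.139, 0.0112 and 0.0407. Of the 3 Cdh1-intact arrays 0 correlated best with their own number. These values gave no sign of a pairing by number. They cannot exclude one, since Cdh1-intact array 2 stood far apart and weighs on all deviations of its group. With the number as a replicate block, 0 genes and 9 lists passed. Fzr1 stayed at −0.61, which a balanced block cannot change. Its limma unadjusted p was 0.0168 with the block (adjusted p = 0.837) and 0.0729 without it. The interferon list was lost (adjusted p = 0.0660) and the adhesion and homing list gained (0.0133), and no other list changed its call. Levels of 3 to 4 or below are near the floor of these arrays, so small differences cannot be read there, as for Cdh1 (E-cadherin), Myc, Cd34 and Hba-a1. Clec1b lay near the floor on all arrays but Cdh1-intact array 1 (4.77), and Rag1 on all but Cdh1-intact array 3 (5.36).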

Other observations

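Of the tests below, those on extra chromosome copies, level classes with arrays left out, cell mixture, an outside sample and handling were chosen only after the result was seen. The genes of this paragraph were also chosen after their values were seen. The Cdkn2a locus, which encodes the tumour suppressors p16Ink4a and p19Arf, lay at 3.38, 5.79 and 10.73 on the Cdh1-intact arrays 1, 2 and 3 and at 10.71, 10.16 and 11.11 on the Cdh1-deficient arrays. Pttg1, the gene for securin, lay at 6.78 on Cdh1-deficient array 2 and at 10.39 to 11.02 on the other 5 arrays. The early B-cell genes Rag1 and Dntt lay at most at 5.36 and 4.52 on any array. The B-lineage gene Vpreb3 lay at 5.09 on Cdh1-intact array 2 and at 10.46 to 11.74 on the others. The erythroid enzyme gene Alas2 lay at 9.31 on Cdh1-intact array 1 and at 4.82 to 5.61 elsewhere. Cym, the one gene called with Xist as a covariate, lay at 4.41, 8.81 and 8.39 on the Cdh1-intact arrays and at 4.39, 4.00 and 4.31 on the Cdh1-deficient arrays.

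Higher expression of genes on chromosomes 3 and 5 in Cdh1-deficient cells may reflect extra copies of these chromosomes in the leukaemias, a hypothesis that stays open, since the share of higher genes (85.9% on the lower of the pair) only restates the pattern and the shift lies below the 0.585 that 3 copies against 2 give on the log2 scale. A few genes or one region of each chromosome are argued against. The lowest median among 3 equal parts of each chromosome by gene order was 0.293, against 0.087 over all genes of the set. The profile of Cdh1-intact array 2 is also argued against. Without that array the median over both chromosomes was 0.303, against 0.050 over the other chromosomes. A trend with signal level would leave no shift over genes of like level on the other chromosomes. That shift was 0.186, 0.332 and 0.291 in 3 equal classes by level. The lowest missed the bound of 0.2 set beforehand, so the test as set did not decide, though a shift remained in every class. No class fell below 0.143 with any 1 array left out, a check added afterwards whose fits share most arrays. GC content was not tested without a genome. The largest chromosome shift was 0.356 in the real split and 0.225 in the highest other split, so only the real split was as large. The 10 splits of 6 arrays are too few to exclude chance.

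Cdh1-intact array 2 had T and NK cell transcripts high and B-lineage transcripts low, although the label and the series describe B-cell leukaemia. On it 14 of 21 T and NK cell genes lay above all other arrays, 10 of them by over 2 on the log2 scale; 0 of the 21 are in another list and 2, Cd2 and Zap70 (the latter named after its values were seen), averaged over 8 on the other 5 arrays. A mixture of T or NK cells with a library that is mostly B-lineage is argued against, because 26 B-lineage genes abundant on the other arrays fell by a median of 3.75 or more (at most 7.45% left, as several reached the floor), 15 of them by over 3, although falls ran from −0.83 to 7.60 and Ikzf1, Ikzf3 and Ptpn6 were higher there. Mycn differed by −0.288 from the lowest other array, and Fzr1, whose probe position is unknown, lay at 8.04 against 8.92 on both other Cdh1-intact and 7.73 to 8.22 on the Cdh1-deficient arrays, which leaves a wrong label on another N-myc sample and an N-myc leukaemia of T or NK profile as possible explanations that cannot be told apart. No biological explanation was tested.

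The fall of immediate early genes in Cdh1-deficient cells is unlikely to come from Cdh1-intact array 2, since the median without that array was −1.39. Handling before or during the GFP sort could give such a pattern and stays open, as the heat shock and unfolded protein response list, which also responds to handling, had a median of −0.199, and the labels give no sorting day or order. A dependence on Cdh1 is the difference the design names and was not tested apart from these.

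The 10 possible splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. With limma, 0 genes passed in the real split and at most 0 in the others, so 10 of 10 gave as many, with 1000 genes at an unadjusted p under 0.05 in the real split and up to 1342 in another. For gene lists the real split gave 9, the highest other split 14, and 6 of 10 splits gave 9 or more.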
